A study of Mus musculus with 2 samples.

How the data were processed

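STAT5 binding was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which DNA bound by a protein is recovered with an antibody and sequenced. The cells were mouse OT-I CD8 T cells, which carry a transgenic T cell receptor for an ovalbumin peptide. Per the labels, they were transferred into mice, primed with that peptide together with agonists of the costimulatory receptors CD134 and CD137, and sorted from the spleen 4 days later. The control group had 1 library of cells without IL-2, and the IL-2 group had 1 library of cells given 0.5 µg/ml IL-2 for 1 hour.

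The authors deposited a table of genes near binding regions, and its peak heights are a signal that is never negative. Per the submitters' processing notes, BWA and the mouse build mm10 were used. The peak caller, the read extension, the depth of each library and any scaling between libraries are not given in the sources used here. The interval names in the deposited table show that regions, called intervals there, were called in each library separately. For each gene the deposited table holds the mean signal height of each library over the gene's regions, the highest peak over both libraries, and the distance of each region from the gene start. It has no highest peak for the control library, so the mean height was used for every ratio, as the rule fixed in advance allowed. No column of per-sample values of other samples was present (0 columns).

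The log2 ratio of a gene was computed as log2 of the IL-2 height plus 5 over the control height plus 5. Ratios of at least 2 and at most 0.5 were counted. With a pseudocount of 5 against a median control height of 5, ratios understate the fold of the heights. A gene was listed because of an interval near it, and all 4934 genes had one in the IL-2 library, so the ratios were selected to favour IL-2. Read counts were not given, so depth and counting error are unknown. With 1 library per group there was no replicate check and no test of IL-2 against control.

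Regions shared by several genes were matched by their interval names, and each region's position was computed from gene start and distance. The position was the same from every gene for 5714 of 5714 intervals. Heights of single regions were solved from the gene means where these determine them, for 2487 of 5703 regions. Gene identifiers were matched to a RefSeq table of assembly GRCm38.p6, which is the mm10 build, and 4799 of 4934 matched.

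There were 23 gene lists fixed before the data were examined. They covered IL-2 STAT5 targets, cytotoxic effectors, cytokines, cytokine receptors, chemokines and their receptors, T cell transcription factors, costimulatory and inhibitory receptors, glycolysis, amino acid transport and mTOR, cell cycle, survival and apoptosis, signalling feedback, memory and homing, interferon response, T cell receptor signalling, and JAK and STAT components. Lists of regulatory T cell, B cell, myeloid, erythroid and megakaryocyte, liver and mammary STAT5 target, unrelated tissue and housekeeping genes served to set other programmes beside these. Lists overlap, since one gene can be a member of several. The share of protein-coding members in the table was compared with all 21900 protein-coding genes of the RefSeq table by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 23 lists. This compares genes in these libraries, not the conditions, and neighbouring genes are not independent. The median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean signal in 10 bins. Wilson intervals have a confidence level of 95% and cover counting of genes or regions only.

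The rule for named genes, also fixed before the data were examined, took the 20 distinct regions with the largest ratio, the 10 with the highest IL-2 peak, the 10 with the lowest ratio, every listed IL-2 STAT5 target, and from every other list the 4 members with the largest absolute log2 ratio. In the first 3 parts of the rule, genes that share a region were named together or by the nearest gene. The ratios ranked there were those of gene means, so a strong single region of a gene with several was averaged with the others. Members of lists were named for themselves, although their regions can be shared with, or lie nearer to, other genes. Some genes that the rule took are not reported here. Genes named outside this rule are stated to be so.

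Alternatives fixed in advance were pseudocounts of 1 and 10, size rules of 1.5 and 4, both libraries scaled to the same median, genes of higher signal only, the highest peak as the IL-2 value, distinct regions, and a distance of 5 kb in place of 1 kb. The highest peak is a maximum over regions set against a mean control height, so it can raise ratios only for genes with more than 1 region. Matching on gene length or on the number of regions, random positions, and leaving out genes with a control interval and T cell receptor segments were added after seeing the data. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. The steps were tested on simulated data for this comparison. Solved heights equalled the simulated ones in 100% of 2487 regions. Of simulated lists drawn from the 4934 genes, 4% of those without a shift fell outside the 2.5 to 97.5 percentiles, and 99.5% of those with a shift lay above them. The shift of 0.5 was added to log2 ratios while the signal bins stayed fixed. In the data a higher IL-2 height also moves a gene to a higher bin. The 99.5% is therefore not the share that the signal-matched percentile would detect in these data. For simulated lists of 25, the number of listed members was drawn at random with members independent of each other. Of these, 6.5% at the background share of the 21900 genes and 99% at an enriched share of 60% passed Fisher's exact test. Members of real lists can share regions, which these draws did not include. The search for STAT motifs in the regions needs a genome sequence and was not run.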

Results

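The design examined where STAT5, a transcription factor activated by the IL-2 receptor, binds in effector CD8 T cells after IL-2. There was 1 library of untreated cells and 1 library of cells given IL-2 for 1 hour. The table held 4934 genes near 5703 distinct regions called in the IL-2 library, on the mm10 build. Of these genes, 3292 had 1 region and 1642 had more. A region could be assigned to several genes, as 1714 of the regions were. Values are peak heights in signal units, without replicates.

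STAT5 signal near several genes of the IL-2 response was high in the IL-2 library and near the median of all listed genes in the control library. The region at Socs2, a feedback inhibitor of cytokine signalling, had a height of 5 in control and 127 with IL-2 (log2 ratio 3.72). Socs1, another inhibitor of that family, went from 6.5 to 107.5, and Cish from 5 to 70.4 over 5 regions. Il2ra, the alpha chain of the IL-2 receptor, had 6 regions with a mean height of 5.5 in control and 81.2 with IL-2. Over all listed genes the median height was 5 in control (interquartile range 4 to 5.8) and 20.75 with IL-2 (15 to 33).

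Intervals were called in the IL-2 library near all 4934 genes and in the control library near 12 of them. The ratio was at least 2 for 4133 genes (83.8%), at most 0.5 for 0, and between for 801. The median log2 ratio was 1.41 (interquartile range 1.08 to 1.94). When both libraries were scaled to the same median over the listed genes, the median log2 ratio shifted by -1.28, 586 genes had a ratio of at least 2 and 20 of at most 0.5. After that scaling 2898 genes were higher with IL-2 and 2036 higher in control. Equal medians over genes listed for an IL-2 interval move many genes to the control side by construction, so these counts show no direction. They are the shares over all genes for the list counts after scaling below. The direction for genes of moderate signal rests on how the libraries were scaled, which is not given in the sources used here.

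**Figure D1:**
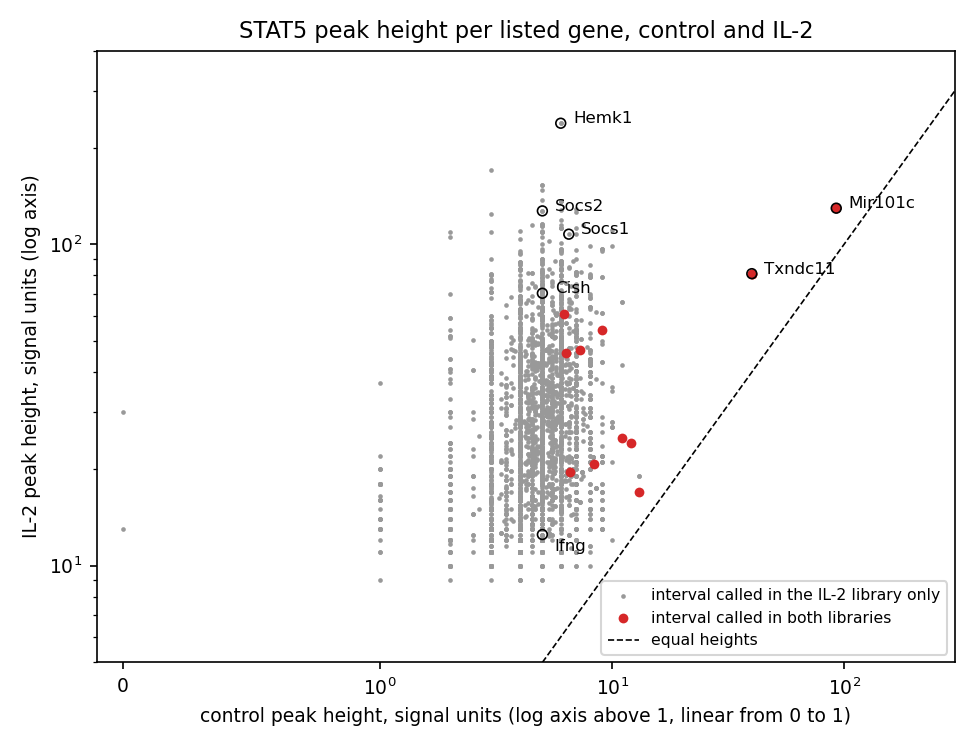
Peak height in signal units of each listed gene in the control library (x axis) and the IL-2 library (y axis), 1 point per gene, on log axes with the x axis linear from 0 to 1. Most control heights lie near the median of 5, while IL-2 heights reach 238, and the genes with an interval in both libraries, in red, include Mir101c at 92.5 and 129.5. The plot uses heights as deposited. Scaling to equal medians would by construction move many genes to the control side (2036 genes), which shows no direction for them.

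The largest ratios, ranked by gene means, fell at regions of varied genes. The largest gene ratio was that of Hemk1 and 6430571L13Rik (log2 ratio 4.47). Their shared region, within Hemk1 on chromosome 9 at 107334560, had heights of 6 and 238. Averaging left out some strong single regions of genes with several. A region of Hist1h2be with 4 and 195 had a larger ratio than that at Hemk1. A region downstream of 2410131K14Rik on chromosome 5 at 118271904 had 3 and 170. Regions with heights above 100 with IL-2 and at most 5 in control lay within Map2k5 (2 and 109), Vprbp (3 and 124), Ptpn4 (2 and 105), Gclm (3 and 109), Ezh2 (5 and 137) and Klhdc1 (4 and 104). Gclm encodes a subunit of the enzyme that begins glutathione synthesis, and Ezh2 a histone methyltransferase. The region of Spata5 and Nudt6 had 5 and 153, and that upstream of Lmna had 5 and 148. A region on the X chromosome at 7570912, upstream of Foxp3 and also assigned to Ppp1r3f and 4930524L23Rik, had 4 and 110. A region of Clstn1 and Pik3cd, which encodes a catalytic subunit of PI3 kinase, had 6 and 128. Il23a, Pan2 and Stat2 shared a region with 5 and 109. The remaining entries among the 20 largest ratios of gene means were named by Gpx8, Tasp1, Mitd1, Serpinb6a, Kdsr and Zbtb12, with log2 ratios from 3.52 to 3.68. For the last 2 entries these were the ratios of Vps4b and Ehmt2, which share a region with the nearest gene. Over all their own regions Kdsr had a log2 ratio of 2.22 (3 regions) and Zbtb12 of 2.585 (2 regions).

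The highest peak, 284, was assigned to Lta, Tnf and Ltb on chromosome 17, which encode cytokines of the tumour necrosis factor family. These genes share several regions, and the table does not determine which of them held the peak. Next were a highest peak of 243 over the 4 regions of Bcl6, that within Hemk1, and peaks of 212 at Tasp1, 196 at Prkcq, 195 at Hist1h2be, 194 at Cdk6, 189 at Cish, 187 at Cubn and 181 at Pik3r5. Bcl6 encodes a transcriptional repressor and Cdk6 a kinase of the cell cycle. The lowest ratios were at genes of low IL-2 height. They included Tnrc18 (10 and 12), Golm1 (8 and 10), Zfpm1 (13 and 17), Clk3 (8 and 11), Tyw5 (7 and 10) and Tcf7, a transcription factor of naive and memory T cells (7 and 11). The others were named by Tor4a, Fam189b, Gm2240 and Nop2, with log2 ratios from 0.34 to 0.42. The ratio of the entry at Gm2240 was that of Snhg7 (9 and 13), which shares a region with it. Gm2240 itself had a log2 ratio of 0.737 over 2 regions.

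Of 30 known IL-2 STAT5 targets, 28 had a region, and 27 of these had a ratio of at least 2, against 4133 of all 4934 listed genes. The share with a region, 93.3% (Wilson interval 78.7 to 98.2%), compares with 19.1% of all 21900 protein-coding genes (adjusted p = 2.36e-17, Fisher's exact test). The median log2 ratio of the list was 2.32, at percentile 85.5 of random lists of like signal. It was at 99.99 with the highest peak as the IL-2 value, and at 100 among random lists matched on region number, an alternative added after seeing the data. The highest peak was set against the mean control height, which raises ratios of genes with several regions, and the list had a median of 3 regions. After scaling to equal medians 25 of the 28 were higher with IL-2 and 10 had a ratio of at least 2. Over all 4934 listed genes, 2898 were higher with IL-2 after that scaling. Bcl2l1, which encodes a protein that protects cells from apoptosis, had heights of 6.75 and 89. Bcl2 had 5.82 and 57.1 over 11 regions and Mcl1 6.75 and 53.8. Lta (6 and 83.8), Osm (4.33 and 67), Bcl6 (4.5 and 75.8), Ccnd2 (6 and 56), Dusp5 (5.25 and 47.3), Socs3 (4.67 and 49.7), Il2rb (5.33 and 48.3), Cdk6 (5.38 and 46.9), Tnfrsf4 (5.75 and 46.8) and Ccnd3 (5.33 and 44.3) followed. IL-2 heights were lower near some genes of effector function and near Myc. Gzmb, a granule protease, had 4.5 and 22, Prf1, which encodes perforin, 4 and 16, and Myc 3 and 13. Ifng had 5 and 12.5, a log2 ratio of 0.81. Prdm1 (5.25 and 35.3), Pim1 (6.17 and 32.3), Nfil3 (4.25 and 32.3), Bcl3 (5 and 32), Pim2 (5 and 24), Il24 (7 and 22) and Id2 (4 and 17) were the other listed members. Dusp6 and Spry1 had no region in the table.

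Cytokine receptors had regions near 19 of 32 members (59.4%, adjusted p = 1.85e-06, Fisher's exact test), each with a ratio of at least 2. Over all listed genes, 4133 of 4934 had such a ratio. After scaling, 16 of the 19 were higher with IL-2, against 2898 of all 4934 genes. Il18rap, a subunit of the IL-18 receptor, had 5 and 105, Il10ra 5.5 and 77, and Il7r 4.5 and 53. The IL-1 receptor family lies in a cluster on chromosome 1, and 5 of its genes were listed there, which apart from Il18rap are named after their values were seen. Il1rl2, the receptor of IL-36, had 2 regions with a mean of 3.5 and 23, at 40315424, within Il1r1, and at 40325344, 717 bp inside the gene. Il1r1 had 3.33 and 21, Il1rl1 5.75 and 53.8, and Il18r1 5.2 and 46.8, and the 4 regions of Il1rl1 lay within Il18r1.

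**Figure D2:**
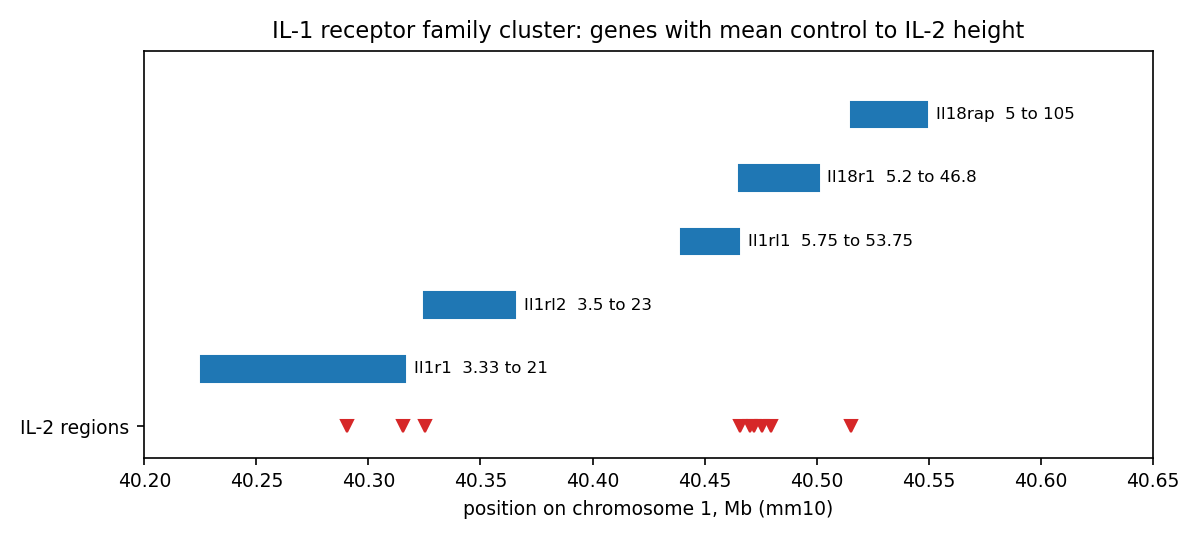
Genes of the IL-1 receptor family (blue bars) along chromosome 1 in Mb of mm10, each with its mean control and IL-2 height in signal units, and the IL-2 regions assigned to them (red triangles). The strongest mean is at Il18rap, with 5 in control and 105 with IL-2, and Il1rl2 had 3.5 and 23.

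Regions lay near most genes of T cell identity. T cell transcription factors had regions near 39 of 48 members (81.3%, adjusted p = 5.03e-19, Fisher's exact test), 36 with a ratio of at least 2. Over all listed genes, 4133 of 4934 had such a ratio. Foxp3 led this list and the regulatory T cell list, of which 10 of 14 members were listed. Irf2 had 5.5 and 66, Id3 8 and 81, and Ikzf4 5.33 and 44. Memory and homing genes were listed for 21 of 23 members, 15 with a ratio of at least 2, among them Cd44 (4 and 45) and Selplg (7.25 and 47). Costimulatory and inhibitory receptors were listed for 22 of 29, led by Tnfrsf18 (6.33 and 75.7), Slamf1 (5.25 and 56.3) and Cd274 (4 and 42). After scaling, 28 of the 39 transcription factors, 11 of the 21 memory genes and 20 of the 22 receptors were higher with IL-2. The share over all genes was 2898 of 4934. T cell receptor signalling genes were listed for 22 of 25, with Prkcq (4.88 and 51.6), Fyn (5.75 and 44.4), Cd8a (6.25 and 42.3) and Lcp2 (6 and 40.3). The median log2 ratio of this list, 1.40, was at percentile 2.85 of random lists of like signal, at 1.25 with a pseudocount of 1, at 2.18 when matched on region number and at 14.7 with the highest peak as the IL-2 value. After scaling 11 of the 22 were higher in control, against 2036 of all 4934 genes.

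Genes of effector molecules and of cytokine signalling were listed in more than the background share. Cytotoxic effectors were listed for 17 of 27 members, with Fasl (7 and 89.7), Gzmk (3.5 and 44.3) and Rab27a (3.83 and 28.3). After scaling 9 of the 17 were higher in control, against 2036 of all 4934 genes. Cytokines were listed for 16 of 30, led by Lta, Tnf and Ltb, and chemokines and their receptors for 15 of 23, with Cxcl10 (4 and 41), Ccl3 (7 and 51) and Ccl5 (4.75 and 40.5). Signalling feedback genes were listed for 19 of 32, with Rgs16 (5 and 78.5), survival and apoptosis genes for 14 of 27 (median log2 ratio at percentile 48.1 of random lists of like signal), with Casp8 (3.75 and 47), and JAK and STAT components for 7 of 11, with Stat4 (5.13 and 42.8) and Jak2 (3 and 17.7). Interferon response genes were listed for 16 of 32, each with a ratio of at least 2, against 4133 of all 4934 genes. Some of these 16 genes share regions, so they are not independent. Irf9 and Stat2, which act downstream of type I interferon, had 5 and 89 and 6 and 66, and Gbp5 had 4.5 and 60.5. The Stat2 mean joined a region near its start with 7 and 23 and a downstream region within Pan2 with 5 and 109. After scaling, 12 of the 16 cytokines, 9 of the 15 chemokine genes, 13 of the 19 feedback genes, 11 of the 14 survival genes, 4 of the 7 JAK and STAT genes and 11 of the 16 interferon genes were higher with IL-2. Over all 4934 genes, 2898 were higher with IL-2. In Fisher's exact test 14 of the 23 lists had a share above the background with an adjusted p under 0.05, those being the lists of this and the preceding paragraphs.

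Metabolic and cell cycle genes did not pass that test. Glycolysis genes were listed for 7 of 25 members (28%, adjusted p = 0.368, Fisher's exact test), among them Eno1 (7 and 74), Eno2 (6 and 48, at a region within Atn1), Slc2a1, a glucose transporter (3.67 and 33.7), and Hk2, a hexokinase (5.6 and 34.6). Amino acid transport and mTOR genes were listed for 5 of 21 (adjusted p = 0.605, Fisher's exact test), led by Slc38a2 (7 and 72), and cell cycle genes for 10 of 29 (adjusted p = 0.0776, Fisher's exact test), led by Pcna (4 and 72, at a region shared with Cds2). After scaling, 6 of the 7 glycolysis genes, 2 of the 5 transport genes and 6 of the 10 cell cycle genes were higher with IL-2. The share over all genes was 2898 of 4934.

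For the lists of other cell types and tissues, the table held 1 of 16 B cell genes (Cd22, 5 and 16), 3 of 19 myeloid genes (Xcr1, Itgax and Cd68), 1 of 18 erythroid and megakaryocyte genes, 1 of 19 STAT5 targets of liver and mammary gland (Igfals, 5 and 59, at a region nearest Nubp2) and 0 of 25 unrelated tissue genes. The last share lay below the background (adjusted p = 0.0135, Fisher's exact test), and the other lists of this paragraph did not pass. Housekeeping genes were listed for 5 of 17, with Rpl13a (5.25 and 29.3) and Tbp (5 and 16). After scaling 3 of the 5, Tbp among them, were higher in control, against 2036 of all 4934 genes.

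**Figure D3:**
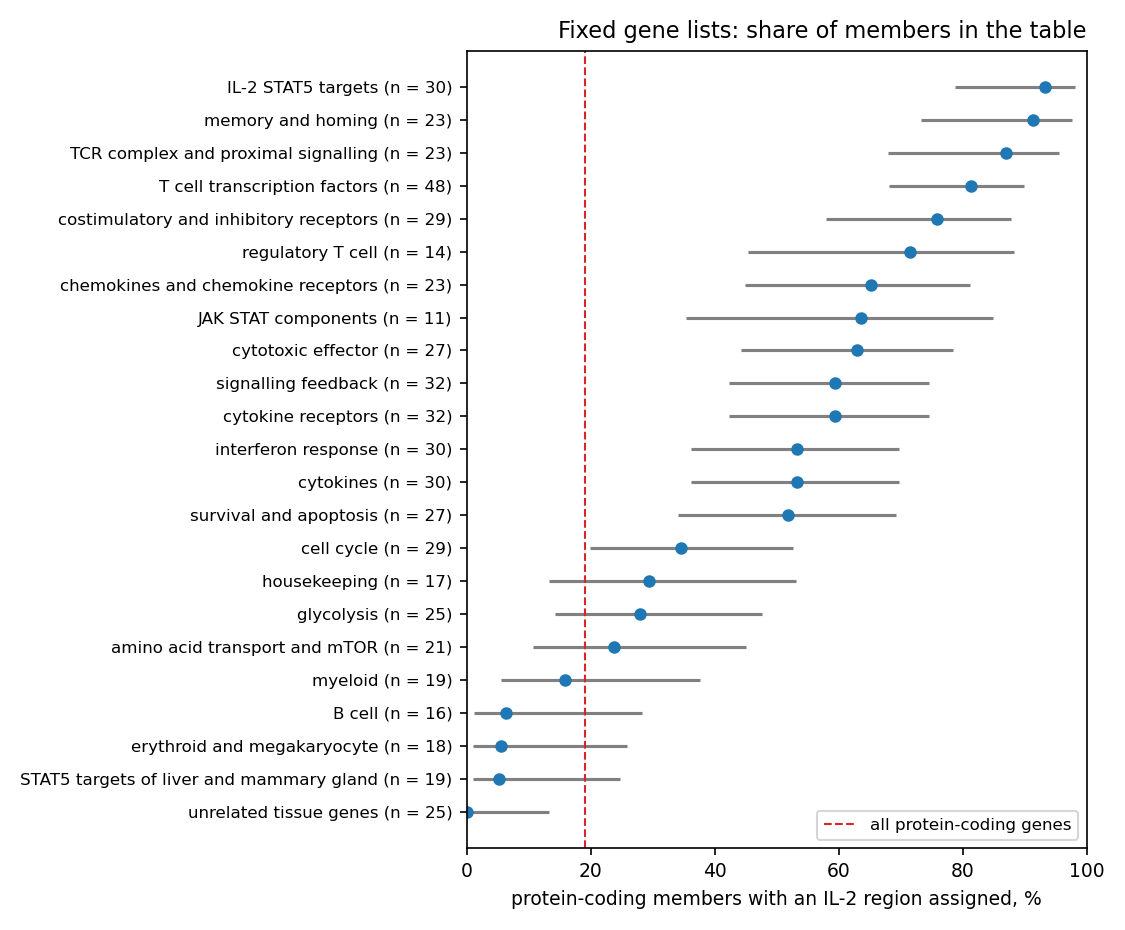
Share of the protein-coding members of each fixed list that had an IL-2 region assigned, in percent, with Wilson intervals as lines and the number of members as n. The dashed line marks the 19.1% of all protein-coding genes. IL-2 STAT5 targets are at 93.3% and unrelated tissue genes at 0%.

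Regions were concentrated at gene starts. Of the 5703 regions, 1569 lay within 1 kb of the start of a listed gene (27.5%, Wilson interval 26.4 to 28.7%), against 2.97% of positions placed at random in the listed genes and their flanks of 10 kb. A further 53.6% lay elsewhere in a listed gene and 18.8% outside. Among regions with a determined height, the median IL-2 height was 16 within 1 kb of a start, 20 elsewhere in genes and 21 outside, with control medians of 4.5, 4 and 5. Regions were not independent of the gene table, which holds only regions near genes. By the interval numbers, 7294 intervals were called in the IL-2 library. Of these, 1591 lay near no listed gene and are left out of the shares given here.

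The 12 genes with a control interval included the strongest control signal. Mir101c, on chromosome 9 near position 3038669, had 92.5 in control and 129.5 with IL-2, and Txndc11 and Zc3h7a shared a region with 40 and 81. The other 9 genes were 2310001H17Rik (6.17 and 60.7), Coro1c (9 and 54), Selplg, Ppp3cc (6.33 and 45.8), Farsb (11 and 25), Erdr1 (12 and 24), Klf2 (8.33 and 20.7), Prkce (6.6 and 19.6) and Zfpm1. Apart from Selplg and Zfpm1 these 12 were named after their values were seen.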

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

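No paired analysis was possible because each group had 1 library. The choices of random lists matched on region number, of random positions and of gene sets matched on length, and the count without control-interval genes, were made after seeing the data. The count of 4133 genes with a ratio of at least 2 became 1141 with the 4-fold rule, 586 with both libraries scaled to the same median, 2453 of the genes of higher signal, and 1996 of the distinct regions with a determined height. The 4-fold rule is stricter, and the last 2 settings hold fewer items by construction. The count also fell with a pseudocount of 10 and rose with a pseudocount of 1. The count at or below 0.5 went from 0 to 20 with scaling and stayed at 0 in the other settings. The median log2 ratio of 1.41 became 2.00 with a pseudocount of 1, 1.06 with 10, 0.13 with scaling, 1.93 for genes of higher signal, 1.53 with the highest peak and 1.32 for distinct regions. Scaling removes any overall difference between the libraries by construction, so it cannot show which value is right.

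No list passed the upper or the lower percentile bound in the main setting (0 and 0). With the highest peak as the IL-2 value, 1 list lay above (IL-2 STAT5 targets, 99.99) and 1 below (memory and homing, 1.78). With a pseudocount of 1, 1 lay below (T cell receptor signalling, 1.25). Matched on the number of regions, 3 lay above (IL-2 STAT5 targets at 100, cytokine receptors at 99.99 and interferon response at 99.19) and 2 below (T cell receptor signalling at 2.18 and myeloid at 2.35). Matching on signal takes up most of the ratio by construction, since control heights vary little, and for the other changes the cause was not tested. In Fisher's exact test 15 lists passed, and 15 did with gene sets matched on length. Of genes with a height at or above the median, 2469 had an IL-2 interval and 9 a control interval. The share of regions near a start was 46.0% within 5 kb, against 13.6% of random positions. Within 1 kb, random positions gave 2.97%.

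Of 108 genes under the naming rule, not all named in the text since 1 gene stood for each shared region, 95 had a ratio of at least 2. With scaling, 6 of these 95 became negative: Cd22 (-0.26), Il24 (-0.30), Prf1 (-0.036), Sesn2 (-0.18), Slc7a1 (-0.036) and Tbp (-0.26), and 32 others of the 95 fell under 2. The 13 genes under 2 in the main setting, Ifng and Itgax among them, were all negative with scaling. A pseudocount of 10 took 7 under 2 and a pseudocount of 1 took 3 above. Depth is unknown, so no counting error could be given. The motif search, with its alternative, was not run.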

Other observations

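Some genes outside the lists, named after their values were seen, also had strong regions. The microRNA gene Mir155 had a region with 7 in control and 82 with IL-2, and the cluster of Mir17 and Mir20a shared a region with 4 and 51. Mir29a and Mir29b-1 shared a region with 11 and 66. In all, 76 of the 1228 genes annotated as microRNAs were listed, against 4187 of 21900 protein-coding genes. Genes with many regions included Tcra with 26, Tcrb with 23, Ubac2 with 20, Foxp1 and Akap13 with 18 each and Sema4d with 13. These numbers were not set against gene length, which ranged from 92396 bp for Sema4d to 1796231 bp for Tcra.

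For the patterns weighed here, the tests on control signal, on T cell receptor segments and on the gene content of X were chosen only after the results were seen, while those on gene length and on X copies were chosen before. Control signal was somewhat higher in stronger regions. The tenth of determined regions with the highest IL-2 height (median 74) had a mean control height of 5.47, and the tenth with the lowest (median 11) had 3.98, a difference of 1.49 (bootstrap interval 1.12 to 1.91). A first form of this test, the difference of medians (5 and 4) against a bound of 2, had counted against prior binding. It was replaced after its result was seen, because ties gave it a bootstrap interval of 1 to 1. The replacement turned that verdict into an open one. By its rule it could only count against prior binding or leave it open. The control heights rose far less than the IL-2 heights, so no proportion between them is shown. More STAT5 bound before IL-2 at strong regions may explain the higher control signal. It cannot be told apart from more open chromatin at those regions, since no input library was used here. Signal not specific to STAT5, for example at repeats, may explain the control intervals near Mir101c (log2 ratio 0.46) and Txndc11, which cannot be told apart from prior binding because the repeat content was not analysed here and the genes were picked for their control signal.

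Protein-coding genes on the X chromosome were listed less often, at 59 of 966 (6.11%, Wilson interval 4.76 to 7.80%), against 4128 of 20665 on autosomes. Gene length would predict 19.5%, which argues against length as the cause. In the 14 lists with an excess, 2 of 7 X members and 215 of 321 autosomal members were listed (p = 0.0464, two-sided Fisher's exact test). Under the first rule this counted against a lack of T cell genes on X, but a minimum of 20 X members was added after the result was seen, since the lists were selected for their excess and 1 more listed member would give p = 0.23 in Fisher's exact test, and with it that explanation stays open. A single X copy may contribute: halved peaks would leave 12.8% of autosomal genes listed, above the X share, but this is an assumed profile and the sex of the mice is not given in the sources used here, so it cannot be excluded.

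Near joining and constant segments of the T cell receptor alpha and beta genes, the median control height over 24 distinct sets of regions was 6.38, against 4 to 5.17 for random sets of like IL-2 height. Not all segments were raised, as Traj58 and Traj59 had 4.8, Traj25 to Traj30 had 5, and the delta joining, diversity and constant genes of the same locus had 5 to 5.5. Variable segments were not in these sets, and those of the beta gene ranged from 2 (Trbv17) to 13 (Trbv12-2 and Trbv13-2). The sets draw on 23 regions and overlap, so they are not independent. Extra copies of receptor DNA in OT-I cells may explain the raised median, but they cannot be told apart from open chromatin at the locus, since no input library was used here.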
